A study of Mus musculus with 76 samples.

How the data were processed

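The samples were alveolar septa and vessels microdissected from lungs of wild-type and Noxo1 knockout mice, per the labels, and 76 arrays from 40 mice were used. RNA was isolated with RNeasy Micro and amplified with Ovation PicoSL WTA V2, labelled with Cy5 and hybridized to Agilent mouse arrays, per the labels' protocols. Per the labels, 4 further arrays without signal were left out by the submitters. The labels name limma, without version or settings. That the deposited values are on the log2 scale and quantile normalized between arrays was read from the values themselves, since quartiles differed by at most 0.0024 between arrays. The background correction is not given in the sources used here. The deposited log2 values ran from 0.94 to 15.79, and column medians lay between 3.19 and 3.192.

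Of 62976 features 31465 carried a gene symbol and 31511 did not. By accession, 29050 named features were matched to a mouse RefSeq list, 2415 were not matched and kept their symbol, and 2933 symbols were updated. Features with an empty cell in any array (671, with 675 cells, 285 of them named) were left out. Of 20863 genes 20710 remained, and the feature with the highest mean was kept for the 6007 genes with several. Pairs of features of 1 gene (n = 856) correlated over arrays at a median of 0.417, and pairs of different genes at 0.0136. Features without a symbol were tested apart. A pair of wild-type control vessel arrays at 3 months, both labelled mouse 25, were averaged to 1 replicate in the fits of vessels. Their correlation was 0.768, within the range of 0.735 to 0.802 of the other pairs of that group.

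Each tissue was fitted with limma 3.58.1 in R 4.3.3 with a mean for each of the 8 groups, eBayes with a trend, and Benjamini and Hochberg adjustment at 0.05 over all genes. Tissue comparisons used all 76 arrays, both mouse 25 arrays included, with duplicateCorrelation by mouse (consensus correlation 0.026). The mouse numbers joined 35 pairs of septa and vessels, whose residuals correlated at a mean of 0.04, against -0.009 for other pairs of the same groups, and 4 pairs were over 0.1. In 24 comparisons the tests covered smoke in each genotype, tissue and time, mean smoke, genotype, interactions, time in controls, and tissue. The splits redrew labels within the other factors, with 100 splits per comparison, while the exact permutation tests of genotype redrew labels within tissue and time with exposures pooled. Adjusted p values of single genes come from limma unless exact or permutation is stated. Files were read with the data.table package (version 1.17.8), and Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for permutations and figures.

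Of 45 gene and cell type lists, fixed before the data were examined, 44 entered camera with a preset correlation of 0.01 and, as an alternative, with a correlation estimated per list. The sex-linked list was used for the sex pattern only. Members were also adjusted over the list alone. In no comparison did camera pass the lists of emphysema proteases, nitric oxide and vasoactive signalling, hypoxia, Noxo1 neighbours, substrain genes, dendritic cells, mast cells, pericytes, lymphatic endothelium, nerve and Schwann cells, or chondrocytes.

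The genes named were set by a rule written before the data were examined. In each comparison these were the 10 largest rises and 10 largest falls among genes past adjustment with a mean above the 25th percentile, without unnamed gene models, or, where none passed, the 3 with the lowest p among genes above that percentile and not unnamed models, so a gene outside these limits can have a lower p. To these were added up to 4 members of each list with a member past, Noxo1 and the NADPH oxidase list in every group, and in interactions the genes named for wild-type smoke. Other genes, among them members past only when adjusted over the list alone, were chosen after their values were seen. Comparisons and groups were likewise fixed before the data were examined, as were the alternatives except those named as chosen later. A list of glucocorticoid-induced genes, used only in the closing section, was written after some of its genes were seen.

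The scripts were tested on simulated data with 50 genes shifted at each size. A shift of 2 log2 units was recovered for 48% of genes in wild-type septa smoke at 8 months, 20% in wild-type vessels, 96% for mean smoke in septa and 86% in vessels, 76% for genotype at 8 months in septa and 56% in vessels, and 22% and 12% for the interaction at 8 months (32% in vessels for 4 log2 units). The alternatives tried were quantile normalization, leaving out the genes under the 25th percentile of signal, the mean of all probes, and array weights. Others were a replicate block, only the groups compared, 1 fit over 76 arrays with a mouse block, and both mouse 25 arrays as replicates. Leaving out each array, mouse as a fixed factor or no block, leaving out group pairs, and the estimated correlation were tried too. Chosen after seeing the data were a sex-linked covariate, leaving out 3 vessel arrays of low correlation, leaving out the arrays of mice 7 and 29, exchanging the genotypes of their vessel arrays, and leaving out each array for Noxo1.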

Results

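Gene expression was measured in microdissected lung tissue of 40 mice on 76 single-colour Agilent arrays. Alveolar septa gave 39 arrays and lung vessels gave 37. The mice were wild-type or lacked Noxo1, which encodes the organiser subunit of the NADPH oxidase NOX1. They were exposed to cigarette smoke at 140 mg of particles per m3 for 6 hours a day on 5 days a week, or kept as controls, and tissue was taken after 3 or 8 months. The 16 groups held 4 or 5 arrays each. The groups of 4 arrays were wild-type control septa at 3 months, knockout control vessels at 3 months, and the smoke-exposed vessels of both genotypes at 8 months. A pair of wild-type control vessel arrays at 3 months carried the number of 1 mouse and were averaged for the tests within vessels, so 36 vessel replicates entered these. The number of arrays limits the precision, because array signals carry no counts. The median correlation of an array with the other arrays of its tissue was 0.839 to 0.898 in septa and 0.693 to 0.819 in vessels. The median residual SD of a gene was 0.738 log2 units in septa and 0.98 in vessels. Odorant and vomeronasal receptor genes (n = 1310) had a median signal of 2.01 and a 95th percentile of 3.97, and 53.3% of the 20710 genes tested had a mean signal above that percentile.

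Noxo1 was examined in every group as a weak check of the genotype labels. The part of the gene that was deleted is not given in the sources used here, so whether its probes lie within it is open. Its signal was low, with a mean of 3.33 over all arrays, which lies below the 95th percentile of the receptor genes. In septa it averaged 2.42 ± 0.67 (SD, n = 20) in knockout and 3.72 ± 1.27 (n = 19) in wild-type mice, a difference of -1.31 ± 0.32 (SE) log2 units, whose size is uncertain since both means lie below that percentile. Of all 20710 genes, Noxo1 had the lowest p for genotype in septa (0.000166, limma), and its adjusted p was 1. In vessels it averaged 3.20 ± 1.25 (n = 18) in knockout and 4.05 ± 1.54 (n = 18) in wild-type mice, a difference of -0.84 ± 0.47 with an adjusted p of 0.979. An exact two-sided permutation test gave a difference of -1.90 in septa at 3 months (10 against 9 mice, p = 0.0011, adjusted over 4 tests 0.00442). The same exact test gave -0.76 in septa at 8 months (adjusted p 0.13), -1.25 in vessels at 3 months (adjusted p 0.119) and -0.46 in vessels at 8 months (adjusted p 0.534). At 3 months the mean Noxo1 signal in septa was 3.98 in wild-type controls and 4.43 in wild-type smoke-exposed mice, against 2.63 and 2.05 in knockout mice. At 8 months the septa means were 3.04 and 3.49 in wild-type and 2.56 and 2.46 in knockout mice. Wild-type vessels averaged 3.55 and 4.93 at 3 months and 3.6 and 4.02 at 8 months, and knockout vessels 3.45 and 2.75, then 3.74 and 2.81. The array labelled knockout control vessel at 8 months, replicate 4, had a Noxo1 signal of 7.03, the highest of all arrays. It is the vessel array of mouse 7, whose arrays may be exchanged with those of mouse 29 in 1 tissue. The means and differences above follow the labels and include the arrays of both mice. Smoke effects on Noxo1 ranged from -0.92 ± 0.95 in knockout vessels at 8 months to 1.38 ± 0.95 in wild-type vessels at 3 months, and none passed adjustment in limma.

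**Figure D1:**
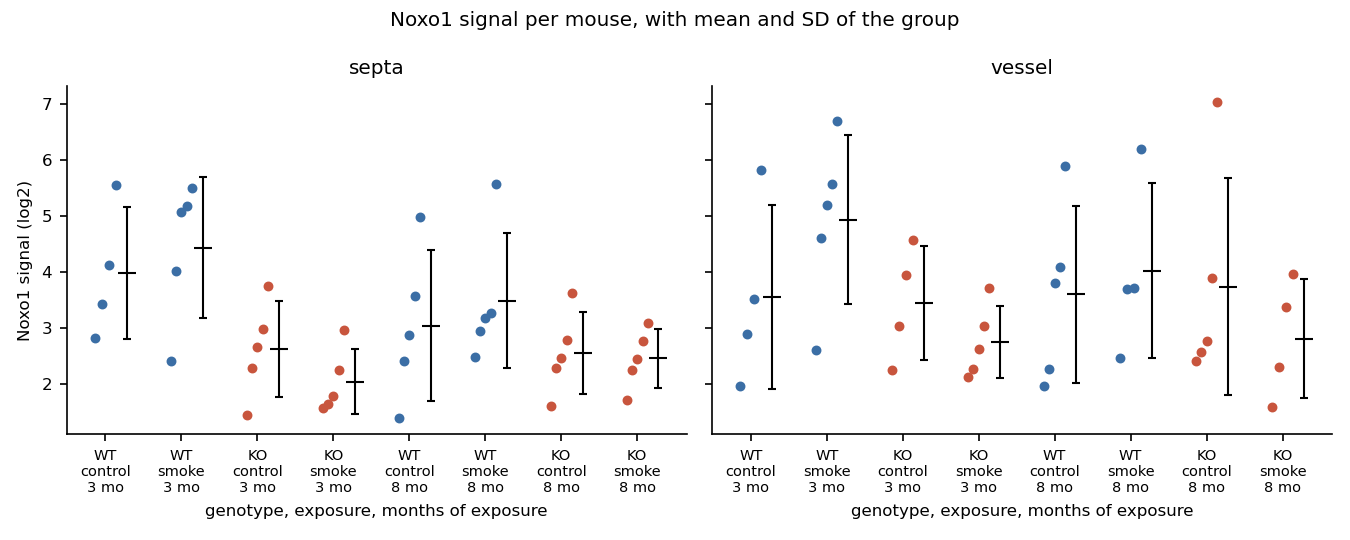
Noxo1 signal (log2) of each mouse by genotype, exposure and months, in septa and in vessels, with the mean and SD of the group beside the points. Knockout septa at 3 months averaged 2.63 and 2.05 against 3.98 and 4.43 in wild-type mice. A vessel array labelled knockout lay at 7.03, that of mouse 7, whose label is in doubt.

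Vessels and septa were compared over 37 and 39 arrays, of 36 and 39 mice, to describe the material. Contractile genes were far higher in vessels. Actc1 was 316-fold higher (log2 8.30 ± 0.31), Cnn1 242-fold and Actg2 184-fold. Acta2, an actin of smooth muscle, was higher by 6.17 ± 0.16 and had the lowest adjusted p of all genes (2.05e-43). Dcn was higher by 6.78, Plin4 by 6.57, Sfrp2 by 6.42, Gabra3 by 6.41, Ccn3 by 6.38 and Ntrk3 by 6.23. Aoc3 was higher by 7.47. In septa Aoc3 (2.5), Ccn3 (2.86), Ntrk3 (2.79) and Gabra3 (3.61) lay below the 95th percentile of the receptor genes, so their differences are lower bounds. Cxcr2 was 15.9-fold and Ripply3 14.6-fold higher in septa than in vessels. Sox11 differed by -4.28 and Apln by -4.02. Gzma (-3.71), Mmp8 (-3.68), Stfa2 (-3.67), Ppbp (-3.66), Fpr2 (-3.65) and Cstdc4 (-3.61) were likewise lower in vessels. Sox11 (3.1), Apln (3.97), Fpr2 (3.3) and Cstdc4 (3.74) were not above that percentile in vessels, so the sizes of these differences are lower bounds too. Over all genes, 5978 differed, of which 2620 were higher and 3358 lower in vessels. An unadjusted p under 0.05 was reached by 7932 genes. Exchanging the tissues within mice at random gave at most 749 genes, so chance can be excluded for this count.

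Smooth muscle markers had a median difference of 3.55, with 12 of 13 higher and 1 lower in vessels (adjusted p 1.07e-09 with an estimated correlation). Type 1 pneumocyte markers had a median of -2.27, and all 10 were lower in vessels, among them Clic5 (-2.12 ± 0.12) and Hopx (-2.42 ± 0.17). All 12 type 2 pneumocyte markers were lower as well, with a median of -1.25 and Lamp3 at -1.85 ± 0.14. Among 12 capillary endothelial markers 10 were lower, including Gpihbp1 (-2.64 ± 0.20) and Sema3c (-2.09 ± 0.15). Complement genes were higher in vessels in 12 of 15 cases, with C4b at 2.86 ± 0.17, C1ra at 1.30 ± 0.09 and C3 at 0.98 ± 0.11. Matrix genes were higher in 21 and lower in 7 of 31 cases, with Col1a2 at 1.81 ± 0.12 and Ltbp4 at 1.31 ± 0.08. Ciliated cell genes had a median of 2.67 (9 of 12 higher), with Foxj1 at 4.72 ± 0.40 and Tmem212 at 5.02 ± 0.37. Club cell genes had a median of 0.69, with Cyp2f2 at 2.29 ± 0.27, and the list was at 0.122 with an estimated correlation. B cell (median -1.55), interferon response (-0.74), DNA damage (-0.70) and neutrophil genes (-0.65) were lower in vessels, with Cd79a at -2.43 ± 0.35, Rsad2 at -2.79 ± 0.38 and S100a8 at -2.69 ± 0.29. Of 12 fibroblast markers 6 were higher and 4 lower in vessels, with a median of 0.90, and skeletal muscle markers had a median of 0.42. In camera 23 of 44 lists differed, and the 13 lists of smooth muscle, both pneumocytes, capillary endothelium, matrix, complement, ciliated cells, B cells, interferon response, DNA damage, neutrophils, fibroblasts and skeletal muscle held with an estimated correlation.

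NADPH oxidase genes were lower in vessels for 7 of 15 members, both adjusted over all genes and adjusted over the list alone. Rac2 (-1.69 ± 0.21), Ncf4 (-1.66 ± 0.26), Cybb (-1.57) and Ncf1 (-1.53) code for the phagocyte enzyme, and Nox4 (-0.67), Cyba (-0.50) and Rac1 (-0.32) were lower too. Noxo1 differed by 0.53 ± 0.28 (adjusted p 0.159). The list had a median of -0.18 and an adjusted camera p of 0.0342, which was 0.0958 with an estimated correlation. The list calls that were lost with an estimated correlation also covered alveolar macrophages (median -0.86, 0.119 with an estimated correlation), T and NK cells (-0.79, 0.0526), erythroid genes (-1.26, 0.342), lysosomal genes (-0.67, 0.114), antigen presentation (-0.62, 0.122), oxidative phosphorylation (0.31, 0.38), club cells (0.69, 0.122), heart muscle of the pulmonary veins (2.13, 0.175) and adipocytes (0.70, 0.122).

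**Figure D2:**
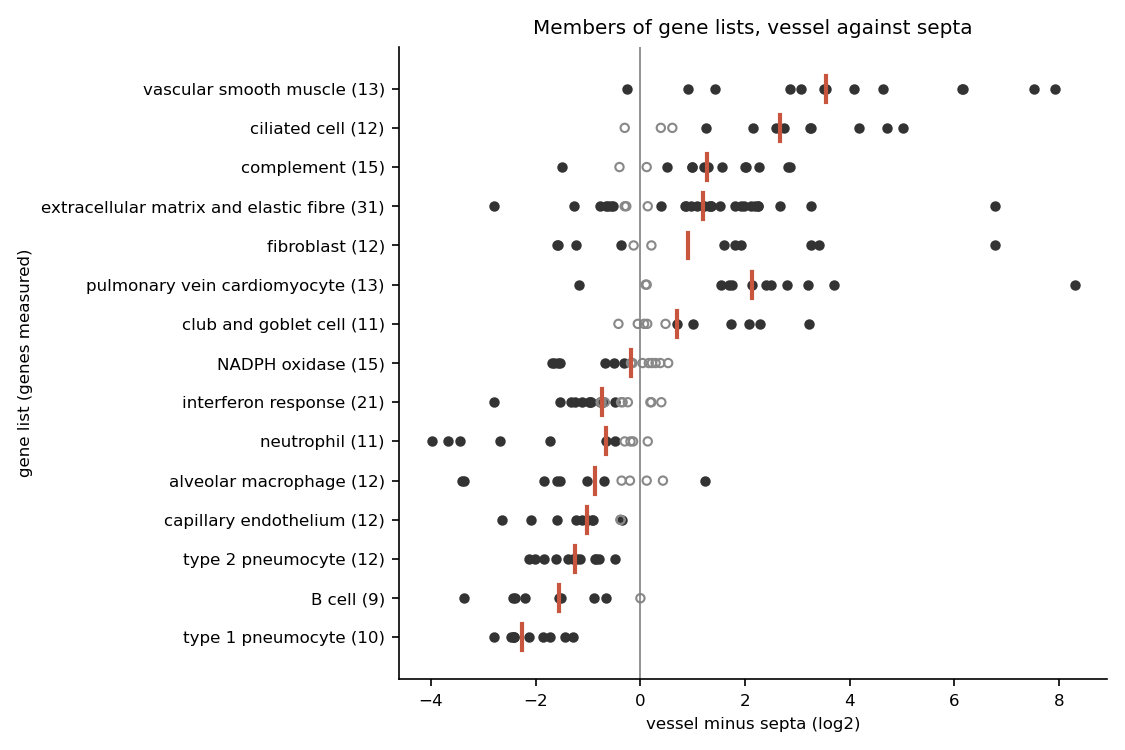
Vessel minus septa difference (log2) of the members of 15 gene and cell type lists, with the number of genes measured in brackets. Filled points passed adjustment over all genes, open points did not, and the red bar is the list median, which ran from -2.27 for type 1 pneumocytes to 3.55 for smooth muscle.

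Smoke was compared with control exposure in each genotype, tissue and time to describe the response of the emphysema and pulmonary hypertension model. In wild-type septa at 3 months, Slc6a14, an amino acid transporter, fell from 5.89 ± 0.87 (SD, n = 4) to 2.39 ± 1.31 (n = 5), a change of -3.50 ± 0.57 (adjusted p 0.00431). The smoke mean lies below the 95th percentile of the receptor genes, so the size of this fall is uncertain. The lowest control lay at 4.62 and the highest smoke-exposed mouse at 4.65. This was the only gene that limma called there, and 1054 genes had an unadjusted p under 0.05 where chance gives 1036. Of 100 splits of the exposure labels, the real one included, 10 called at least 1 gene and the highest other called 3, so chance cannot be excluded. The call for Slc6a14 ended without control replicate 3 or 4, with only the groups compared and in 1 fit over 76 arrays. Immediate early and heat shock genes had a median of 0.60 (17 of 21 above 0, Hsph1 1.44 ± 0.48, adjusted camera p 0.000957, 0.899 with an estimated correlation). Type 1 pneumocyte markers had a median of -0.41 (all 10 below 0, Rtkn2 -1.28 ± 0.58, adjusted p 0.000957, 0.899 with an estimated correlation).

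In wild-type septa at 8 months limma called 0 genes, with 1199 at an unadjusted p under 0.05. Where no gene passed, the genes named are the 3 with the lowest p among those eligible, which have a mean signal above the 25th percentile and are not unnamed gene models. These were Trappc3 (-3.03 ± 0.73), Syt7 (-2.18 ± 0.54) and Suox (-1.91 ± 0.48), each with an adjusted p of 0.734. Trappc3 (3.59) and Syt7 (2.41) lay below the 95th percentile of the receptor genes with smoke, so the sizes of their falls are uncertain. Marco (2.27 ± 0.77) and Atp6v0d2 (2.86 ± 0.91), both markers of alveolar macrophages, passed when adjusted over the list alone (0.0305), as did the aryl hydrocarbon receptor target Cyp1a1 (2.70 ± 0.79, 0.0163). No list passed camera there. The sex-linked genes showed a female pattern in 1 of 5 controls and 3 of 5 smoke-exposed mice of this comparison.

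In wild-type vessels at 3 months limma called 0 genes, with 1267 at an unadjusted p under 0.05. LTO1 (-3.79 ± 0.82), Cacybp (3.91 ± 0.86) and Mmp17 (-3.93 ± 0.89) had the lowest p of the eligible genes and failed the correction (adjusted p 0.368), while 1 fit over 76 arrays called 34 genes. Oxidative phosphorylation genes had a median of -0.58, and all 21 lay below 0 (Cox5a -1.27 ± 0.52, adjusted camera p 5.59e-05, 0.536 with an estimated correlation). Antigen presentation genes had a median of 0.58 (13 of 16 above 0, H2-Aa 1.23 ± 0.42, adjusted p 0.00219, 0.536 with an estimated correlation). Inflammatory genes (median 0.33, Ccl2 2.66 ± 1.04), immediate early genes (median 0.38) and arterial and venous endothelial markers (median -0.56, Sox17 -1.14 ± 0.50) each had an adjusted camera p of 0.0309, which became 0.536, 0.646 and 0.536 with an estimated correlation. In wild-type vessels at 8 months limma again called 0 genes, with 609 at an unadjusted p under 0.05. Dlgap5 (-2.60 ± 0.68), Trp73 (2.80 ± 0.75) and Cdkn2d (-1.72 ± 0.47) had the lowest p of the eligible genes, each with an adjusted p of 1. LTO1 at 3 months (3.61) and Dlgap5 at 8 months (2.45) with smoke lay below the 95th percentile of the receptor genes. So did Trp73 in controls at 8 months (3.85), and the sizes of these differences are uncertain. Erythroid genes had a median of 2.13 and all 6 lay above 0 (Slc4a1 2.12 ± 0.79, adjusted camera p 0.00064, 0.432 with an estimated correlation). The female pattern was seen in 0 of 5 controls and 3 of 4 smoke-exposed vessels at 8 months.

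In knockout mice limma called 0 genes with smoke in each of the 4 comparisons. The counts at an unadjusted p under 0.05 were 733 and 1357 in septa at 3 and 8 months, and 1283 and 891 in vessels. In knockout septa at 3 months Cst13 (-2.26 ± 0.54), Grhl1 (-3.71 ± 0.93) and Eef1akmt2 (-2.24 ± 0.64) had the lowest p of the eligible genes and failed (adjusted p 0.999). All 3 lay below the 95th percentile of the receptor genes with smoke (2.16, 3.46 and 3.26), so these sizes are uncertain. Erythroid genes had a median of -1.55 there (0 of 6 above 0, Hbb-bt -2.16 ± 0.80, adjusted camera p 9.87e-05) and B cell genes a median of 0.70 (8 of 9 above 0, adjusted p 0.0362), and both were at 0.841 with an estimated correlation. In knockout septa at 8 months Nudt19 (2.73 ± 0.57), Fam149a (-2.43 ± 0.54) and Tubb2a (1.33 ± 0.30) had the lowest p of the eligible genes (adjusted p 0.334), with Nudt19 below that percentile in controls (3.57). Immediate early genes had a median of -0.98 and all 21 lay below 0 (adjusted camera p 5.46e-07, 0.447 with an estimated correlation), and Egr1 (-1.85 ± 0.63), Nr4a1 (-1.40 ± 0.48), Fosb (-2.66 ± 0.92) and Fos (-1.49 ± 0.53) passed when adjusted over the list alone (0.0411). Alveolar macrophage markers had a median of 0.90 (11 of 12 above 0, adjusted p 0.00152, 0.476 with an estimated correlation), and Marco (2.47 ± 0.77), Ctsk (2.34 ± 0.83) and Plet1 (1.64 ± 0.60) passed when adjusted over the list alone. The female pattern was seen in 0 of 5 controls and 4 of 5 smoke-exposed mice there, so smoke and sex were partly confounded.

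In knockout vessels at 3 months Pgghg (3.30 ± 0.65), Olfml1 (4.27 ± 0.89) and Mkrn2 (4.43 ± 0.95) had the lowest p of the eligible genes and failed (adjusted p 0.235), while 1 fit over 76 arrays called 23 genes. The control means of Olfml1 (1.91) and Mkrn2 (1.75) lay below the 95th percentile of the receptor genes, so the sizes of their differences are uncertain. Immediate early genes had a median of -0.79 (20 of 21 below 0, adjusted camera p 0.000114, 0.909 with an estimated correlation), and Hspa1a (-3.52 ± 1.01) and Hsph1 (-1.92 ± 0.63) passed when adjusted over the list alone. Heart muscle markers of the pulmonary veins had a median of 2.38 (adjusted p 0.0232, 0.909 with an estimated correlation). In knockout vessels at 8 months Palm (1.78 ± 0.38), Tmem50b (1.39 ± 0.31) and Sync (-2.95 ± 0.66) had the lowest p of the eligible genes (adjusted p 0.402), and 1 fit over 76 arrays called 2 genes. The female pattern was seen in 1 of 5 controls and 3 of 4 smoke-exposed vessels there, and in 1 of 4 and 3 of 5 at 3 months, so smoke and sex were partly confounded. Type 2 pneumocyte markers had a median of 0.58 (10 of 12 above 0, Sftpd 1.48, adjusted camera p 0.000385) and smooth muscle markers a median of -0.44 (all 13 below 0, Mylk -1.26, Myocd -1.68, adjusted p 0.00259). NRF2 antioxidant targets (median 0.47, Gclc 2.18 ± 0.65, Gsr 1.60 ± 0.51, adjusted p 0.025), aryl hydrocarbon receptor targets (0.57, Tiparp 1.47, adjusted p 0.0431), inflammatory genes (0.34, adjusted p 0.0259), monocyte genes (0.69, Cd14 2.97, adjusted p 0.0259), lysosomal genes (0.47, adjusted p 0.0259), club cell genes (0.86, Scgb3a1 2.32, adjusted p 0.0113), type 1 pneumocyte genes (0.70, adjusted p 0.0431) and immediate early genes (-0.33, adjusted p 0.0431) also passed camera. With an estimated correlation the lowest adjusted p of these 10 lists was 0.38. Ccl6 (2.01 ± 0.51, 0.0113) and Cybb (4.00 ± 1.19, 0.029) passed when adjusted over the list alone.

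**Figure D3:**
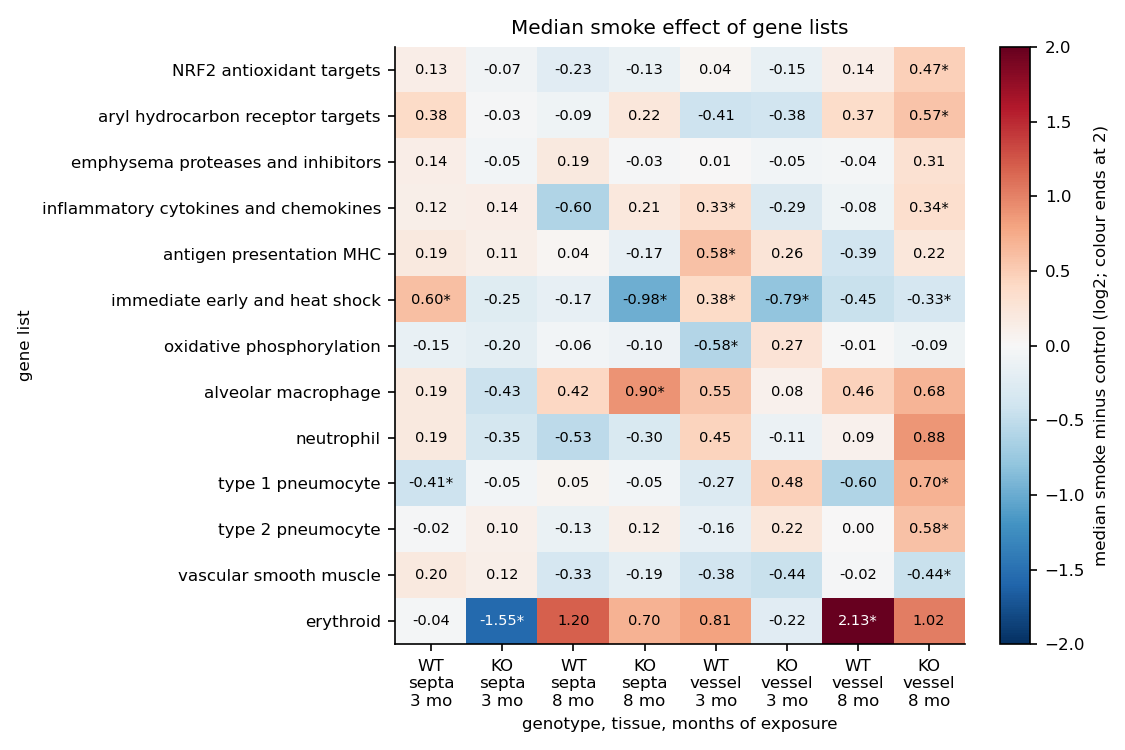
Median smoke minus control difference (log2) of 13 gene and cell type lists in the 8 combinations of genotype, tissue and months, with a star where the adjusted camera p at the preset correlation was under 0.05. Erythroid genes ran from -1.55 in knockout septa at 3 months to 2.13 in wild-type vessels at 8 months.

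Averaged over genotypes and times, Marco was the eligible gene with the lowest p for smoke in septa. A female pattern was seen in 4 of 19 control and 10 of 20 smoke-exposed septa, so smoke and sex were partly confounded. Marco averaged 8.65 in smoke-exposed and 6.83 in control mice (20 against 19 mice, 1.82 ± 0.39), failed adjustment over all genes (0.331) and passed when adjusted over the list alone (0.000384). Flnc (-1.49 ± 0.33) and Lamc3 (-1.29 ± 0.30) followed and failed. Both lay below the 95th percentile of the receptor genes with smoke (2.56 and 3.88), so these sizes are uncertain. Cyp1a1 (1.36 ± 0.40), Lrat (0.78 ± 0.24) and Nqo1 (1.34 ± 0.46), all aryl hydrocarbon receptor targets, passed when adjusted over the list alone (0.0163, 0.0163 and 0.0226). Gpnmb (1.27 ± 0.39) and Hexa (0.75 ± 0.24) of the lysosomal list passed in the same way (0.0422), as did the prostacyclin synthase gene Ptgis (-0.83 ± 0.25, 0.0453). These list members were not named by the rule fixed in advance and were chosen after their values were seen. Over all genes limma called 0, with 1594 at an unadjusted p under 0.05 where chance gives 1036, and no list passed camera. At that unadjusted p, 2 of 100 splits, the real one included, gave as many genes, and the highest other gave 1879. NRF2 targets had a median of -0.06, proteases and inhibitors of emphysema 0.05, nitric oxide and vasoactive genes -0.05 and hypoxia genes -0.14.

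In vessels Tmem203 (-1.95 ± 0.36, adjusted p 0.0845), LTO1 (-2.08 ± 0.41, adjusted p 0.123) and Gkap1 (-1.61 ± 0.35, adjusted p 0.328) had the lowest p of the eligible genes for smoke and failed the correction. Limma called 0 genes, and 5 in 1 fit over 76 arrays, and 1036 had an unadjusted p under 0.05, the number that chance gives. Smooth muscle markers had a median of -0.35 with all 13 below 0 (Mylk -0.56, Cnn2 -0.37, Acta2 -0.26, adjusted camera p 7.45e-05, 0.464 with an estimated correlation). Erythroid genes had a median of 0.98 with all 6 above 0 (adjusted p 0.00861, 0.516 with an estimated correlation) and immediate early genes one of -0.34 (adjusted p 0.00861, 0.534 with an estimated correlation). Neutrophil (0.38, adjusted p 0.0236), lysosomal (0.28, adjusted p 0.0263), alveolar macrophage (0.31, adjusted p 0.0292), type 2 pneumocyte (0.20, adjusted p 0.0335), inflammatory (0.17, adjusted p 0.0411) and antigen presentation genes (0.13, adjusted p 0.0411) passed camera too. With an estimated correlation the lowest adjusted p of these lists was 0.464. Ccl6 (0.93 ± 0.26, 0.0263) and Ncf4 (1.52 ± 0.44, 0.0225) passed when adjusted over the list alone. Xist differed by 2.85 and Eif2s3y by -2.24, and a female pattern was more frequent among the smoke-exposed vessels. Across the 10355 genes with the higher signal, smoke effects of different mice in the same tissue correlated at -0.028 to 0.208, the highest between wild-type and knockout septa at 8 months. These correlations are across genes, which are not independent replicates.

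Knockout and wild-type mice were compared at each time, averaged over exposures, to describe the effect of the genotype. At 3 months a female pattern was seen in 2 of 5 control and 3 of 5 smoke-exposed knockout septa, against 1 of 4 and 0 of 5 in wild-type septa. In vessels it was seen in 1 of 4 and 3 of 5, against 1 of 5 and 0 of 5, so genotype and sex were partly confounded at 3 months. Limma called 0 genes in all 4 comparisons, with 914 and 944 at an unadjusted p under 0.05 in septa at 3 and 8 months, and 1325 and 726 in vessels. In septa at 3 months Npr3, the natriuretic peptide clearance receptor (1.5 ± 0.30, adjusted p 0.213), Angptl4 (1.16 ± 0.26) and Slc38a4 (2.51 ± 0.58, both 0.46) had the lowest p of the eligible genes, with Slc38a4 at 2.59 in wild-type septa, below the 95th percentile of the receptor genes. Noxo1 itself (-1.87 ± 0.46) passed when adjusted over the NADPH oxidase list alone (0.00278). Immediate early genes had a median of -0.63 and all 21 lay below 0 (adjusted camera p 5.68e-09, 0.421 with an estimated correlation), and Dnajb1 (-0.90 ± 0.24) and Egr1 (-1.37 ± 0.46) passed when adjusted over the list alone. In septa at 8 months Angptl6 (-2.07 ± 0.49), Map1b (2.85 ± 0.70) and Srl (1.59 ± 0.40) had the lowest p of the eligible genes (adjusted p 0.835), and Map1b (3.39) and Srl (1.7) in wild-type septa lay below that percentile. Alveolar macrophage markers had a median of 0.67 (11 of 12 above 0, Marco 1.52, adjusted camera p 0.00824, 0.877 with an estimated correlation).

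In vessels at 3 months Uprt (-3.18 ± 0.60, adjusted p 0.112), Ccr8 (2.47 ± 0.54) and Nmd3 (-2.91 ± 0.66, both 0.37) had the lowest p of the eligible genes, and 1 fit over 76 arrays called 27 genes. Uprt (2.32) and Nmd3 (2.6) in knockout and Ccr8 (3.02) in wild-type vessels lay below the 95th percentile of the receptor genes. The sizes of their differences are uncertain. Arterial and venous endothelial markers had a median of -0.60 (11 of 12 below 0, adjusted camera p 0.000191, 0.107 with an estimated correlation), and Slc6a2 (-2.83 ± 0.82) and Sox17 (-1.04 ± 0.35) passed when adjusted over the list alone. Ciliated cell (1.05, adjusted p 0.00129), club cell (0.94, adjusted p 0.0442), immediate early (-0.56, adjusted p 0.015) and heart muscle genes (-1.40, adjusted p 0.015) also passed camera, and all 4 were at 0.708 with an estimated correlation. In vessels at 8 months plasma cell genes were higher in knockout mice, with a median of 1.34 and 7 of 8 above 0 (adjusted camera p 6.21e-06). This was the only list outside the tissue comparison that also held with an estimated correlation (0.0158). List p values were adjusted over the 44 lists of a comparison, not over the 23 comparisons outside tissue. A single such call may thus be chance. Jchain, the joining chain of secreted immunoglobulins, differed by 6.16 ± 1.29, which failed adjustment over all genes (0.626) and passed when adjusted over the list alone (0.000242) and in 1 fit over 76 arrays (6.18 ± 1.12, adjusted p 0.011). Derl3 (2.19 ± 0.75), Tnfrsf17 (1.91 ± 0.78) and Mzb1 (1.91 ± 0.79) passed when adjusted over the list alone. After Jchain, Lmbr1 (2.16 ± 0.50) and Nup37 (-2.55 ± 0.62) had the lowest p of the eligible genes and failed. Lmbr1 (2.38) in wild-type and Nup37 (2.56) in knockout vessels lay below the 95th percentile of the receptor genes. Jchain averaged 10.77 ± 1.81 (SD, n = 9) in knockout and 4.69 ± 3.91 (n = 9) in wild-type vessels by their labels, a difference of 6.08 (exact p 0.0016, adjusted over 4 tests 0.00642). Jchain was tested so because of its rank, which makes this p too small. The wild-type vessels ran from 1.12 to 11.09, with 6 below the lowest knockout value of 7.42. Several wild-type values lay below the 95th percentile of the receptor genes, so the size of the difference in Jchain is uncertain. In septa the same exact test gave 0.42 at 8 months (p 0.686) and -1.17, the other direction, at 3 months (p 0.15). The vessel arrays of mice 7 and 29, which carry opposite genotype labels and may be exchanged, are among these, and without the arrays of both mice the difference in Jchain was 6.05 ± 1.30. With the genotypes of these vessel arrays exchanged it was 4.90 ± 1.41 (limma adjusted p 0.999), and the plasma cell list still passed with an estimated correlation (0.00293, and 0.00452 without both mice). Matrix genes had a median of -0.24 there (27 of 31 below 0, Lox -1.65, adjusted camera p 4.56e-05, 0.359 with an estimated correlation). The 20 neighbours of Noxo1 on chromosome 17 had medians of -0.06 and -0.04 in septa and -0.08 and -0.08 in vessels. Genes that differ between C57BL/6J and C57BL/6N mice had medians of -0.07 and 0.12 in septa and 0.04 and -0.14 in vessels, and neither list passed camera.

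**Figure D4:**
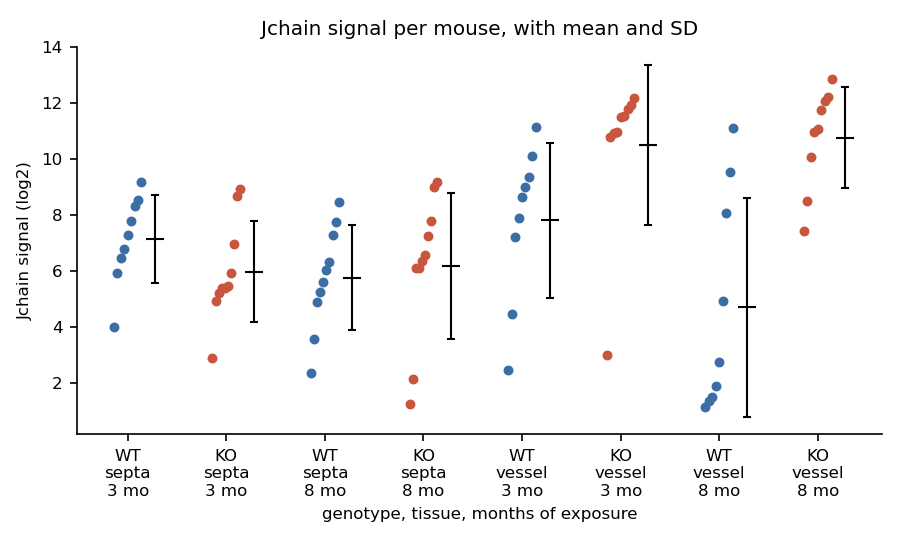
Jchain signal (log2) of each mouse by genotype, tissue and months, exposures pooled, with the mean and SD beside the points. In vessels at 8 months the arrays labelled knockout averaged 10.77 and those labelled wild-type 4.69, with mice 7 and 29 included.

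The smoke effect was compared between genotypes by an interaction term, knockout minus wild-type. At 3 months a female pattern was seen in 2 of 5 control and 3 of 5 smoke-exposed knockout septa, against 1 of 4 and 0 of 5 in wild-type septa. In vessels it was 1 of 4 and 3 of 5, against 1 of 5 and 0 of 5. In septa at 8 months it was 0 of 5 and 4 of 5, against 1 of 5 and 3 of 5. Interaction and sex were thus partly confounded in these comparisons. Limma called 0 genes in all 4 comparisons, but of simulated interactions of 2 log2 units at 8 months it recovered only 22% in septa and 12% in vessels, so interactions of this size are not excluded. There were 698 and 899 genes at an unadjusted p under 0.05 in septa at 3 and 8 months, and 1249 and 650 in vessels. Slc6a14, which fell with smoke in wild-type septa at 3 months, changed by -0.17 ± 0.53 in knockout septa, and the interaction of 3.33 ± 0.78 failed the correction (adjusted p 0.933). Its size is uncertain, since the mean in wild-type smoke-exposed septa was below the 95th percentile of the receptor genes (2.39), and so are those of other genes below that percentile on a side of the contrast, among them Tnni3k, Ddc, Trip11, Car14 and Sox11. Dnaja1 (-1.58 ± 0.38) and Tnni3k (2.76 ± 0.66) followed. Of the genes named in wild-type septa at 8 months, Trappc3 changed by 0.46 in knockout mice (interaction 3.49), Syt7 by 0.04 (2.23) and Suox by 0.17 (2.08), and Fam149a (-3.13 ± 0.76), Prg4 (-3.36 ± 0.90) and Ddc (4.46 ± 1.20) had the lowest p of the eligible genes (adjusted p 0.998). In vessels at 3 months Gtf2e2 (6.52 ± 1.30, adjusted p 0.159), Wipf2 (-6.21 ± 1.31, 0.235) and Trip11 (5.21 ± 1.18, 0.381) had the lowest p of the eligible genes, 1 fit over 76 arrays called 13 genes, and LTO1, Cacybp and Mmp17 had interactions of 2.37, -4.29 and 3.59. In vessels at 8 months these were Palm (2.07 ± 0.54), Car14 (-4.20 ± 1.13) and Sox11 (4.42 ± 1.26, adjusted p 1), and Dlgap5, Trp73 and Cdkn2d had interactions of 2.70, -2.61 and 1.06.

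Immediate early and heat shock genes had a lower smoke effect in knockout than in wild-type mice in 3 of the interactions. Their median interaction was -0.72 in septa at 3 months (19 of 21 below 0, adjusted camera p 0.000155, 0.875 with an estimated correlation), -0.31 in septa at 8 months (19 of 21 below 0, adjusted p 0.0447, 0.873 with an estimated correlation) and -1.20 in vessels at 3 months (20 of 21 below 0, adjusted p 3.83e-06, 0.551 with an estimated correlation). Hspa1a (-5.87 ± 1.43) and Hsph1 (-3.33 ± 0.88) passed in these vessels when adjusted over the list alone. Septa and vessels at 3 months came largely from the same mice, and Egr1 of this list correlated at 0.85 between the tissues of a mouse. The interactions of this list in septa and vessels at 3 months are thus not independent. Oxidative phosphorylation genes had a median interaction of 0.74 in vessels at 3 months, all 21 above 0 (adjusted p 6.13e-05, 0.698 with an estimated correlation). Heart muscle markers (3.02, adjusted p 0.00418) and arterial and venous endothelial markers (0.83, adjusted p 0.0465) also passed there, with 0.884 and 0.551 with an estimated correlation. In septa at 3 months type 1 pneumocyte markers (0.42, all 10 above 0) and erythroid genes (-1.63, all 6 below 0) had an adjusted camera p of 0.0237, and both were at 0.875 with an estimated correlation. In septa at 8 months inflammatory (0.54), interferon response (-0.55), B cell (-0.91) and club cell genes (0.91) had an adjusted camera p of 0.0414, and the lowest was 0.736 with an estimated correlation. In vessels at 8 months type 2 (0.94) and type 1 pneumocyte markers (0.81) had an adjusted camera p of 0.017, monocyte (1.20), inflammatory (0.75) and cell cycle genes (0.44) one of 0.0396, and antigen presentation genes (0.53) one of 0.0414. The lowest of these 6 was 0.629 with an estimated correlation.

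The smoke effect at 8 months was set against that at 3 months, averaged over genotypes. In septa at 8 months a female pattern was seen in 0 of 5 knockout and 1 of 5 wild-type controls, against 4 of 5 and 3 of 5 smoke-exposed mice. At 3 months these were 2 of 5 and 1 of 4, against 3 of 5 and 0 of 5. Vessels were likewise uneven at 8 months (1 of 5 and 0 of 5, against 3 of 4 and 3 of 4), so sex was partly confounded with this contrast. Limma called 0 genes in septa and 0 in vessels (1 in vessels in 1 fit over 76 arrays), with 1232 and 1039 at an unadjusted p under 0.05. Slc9a9 (3.43 ± 0.72, adjusted p 0.42), Derl3 (-2.35 ± 0.52) and Yipf1 (-1.26 ± 0.29, both 0.55) had the lowest p of the eligible genes in septa, and Adamdec1 (3.65 ± 0.81), Rtf2 (4.06 ± 0.92, both 0.642) and Vgll3 (-3.74 ± 0.90, 0.766) in vessels. Slc9a9, Derl3, Adamdec1 and Rtf2 lay below the 95th percentile of the receptor genes on a side of the contrast, so these sizes are uncertain. In septa alveolar macrophage markers had a median of 1.01 and lysosomal genes one of 0.39 (both with an adjusted camera p of 0.00783), and immediate early genes had a median of -0.73 (adjusted p 1.07e-05). Erythroid genes had a median of 1.47 (all 6 above 0, adjusted p 0.00045), and 4 passed when adjusted over the list alone, among them Hbb-bt (2.54) and Alas2 (2.89). With an estimated correlation these lists were at 0.558, 0.499, 0.499 and 0.558. In vessels the clock genes Dbp (5.58 ± 1.39), Cry2 (1.38 ± 0.47), Nr1d2 (1.12 ± 0.42) and Arntl (-3.77 ± 1.05) passed when adjusted over the list alone. Of the variance of Dbp in vessels 55.3% lay between mice of the same group. The clock list had a median of 0.60 and mesothelial markers one of -0.77 (adjusted camera p 0.0343), antigen presentation genes one of -0.58 (adjusted p 0.00503) and aryl hydrocarbon receptor targets one of 1.07 (adjusted p 0.0247). The lowest adjusted p of these lists was 0.218 with an estimated correlation. The smoke effect differed between vessels and septa for 2 genes, with 1279 at an unadjusted p under 0.05. Rnf130 differed by 1.5 ± 0.27 (adjusted p 0.00896) and LTO1 by -2.50 ± 0.48 (adjusted p 0.0206). Of 100 splits, the real one included, 3 called at least 2 genes and the highest other called 2. With mouse as a fixed factor 0 genes passed (LTO1 0.0892, Rnf130 0.113), as without the knockout or the wild-type pairs of groups at 3 months. Neutrophil (0.59) and smooth muscle markers (-0.44) had an adjusted camera p of 0.0404 and erythroid genes (0.94) one of 0.0483, and all were at 0.848 with an estimated correlation.

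In 19 comparisons, all of smoke, its change over time, genotype or their interaction, limma called 0 genes. Any split equals or exceeds a count of 0, so the splits test nothing there. Other splits of wild-type vessels at 3 months called up to 15 genes and those of the smoke effect over time in septa up to 17, against 0 in the real grouping.

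The controls at 8 and 3 months were compared to separate time from exposure. In septa 99 genes differed (10 against 9 mice, 63 higher and 36 lower at 8 months, 2220 at an unadjusted p under 0.05). Splits of the time labels called at most 1 gene otherwise, so a random grouping can be excluded, but the count is not stable. It was 29 without knockout control replicate 3 at 3 months, 38 and 59 without wild-type control replicates 4 and 1 at 3 months, and 5 in 1 fit over 76 arrays. A female pattern was seen in 2 of 5 knockout and 1 of 4 wild-type control septa at 3 months, and in 0 of 5 and 1 of 5 at 8 months. With the sex-linked pattern as covariate 111 genes passed, 87 of them among the 99. Mmp8 was 6.10-fold higher (2.61 ± 0.56, adjusted p 0.0179), Wfdc21 rose by 2.54 ± 0.49, Cd14 by 2.46 ± 0.47 and Adam8 by 2.33 ± 0.46. S100a8 (1.62 ± 0.36), S100a9 (0.98 ± 0.21) and Retnlg (1.63 ± 0.40) rose too, so 4 of 11 neutrophil markers passed, both over all genes and adjusted over the list alone. The neutrophil list had a median of 0.23 with 6 members above and 5 below 0 (adjusted camera p 0.0406, 0.686 with an estimated correlation). Atg2a (2.53), Prcd (2.26), Fancl (1.97), Zfp51 (1.94), Rab44 (1.92) and Rdh12 (1.87) completed the 10 largest rises. The largest falls were in Lrrc17 (-2.70 ± 0.60), Frmpd1 (-2.42), Krtap5-4 (-2.39), Rgag4 (-2.33), Cwc27 (-2.21), the urokinase gene Plau (-2.20 ± 0.48), Tram2 (-1.79), Abcb1a (-1.77 ± 0.40), Gng8 (-1.60) and Olfml3 (-1.34 ± 0.31). Lrrc17 (1.92), Frmpd1 (3.02), Krtap5-4 (3.47) and Cwc27 (2.77) at 8 months lay below the 95th percentile of the receptor genes. So did Prcd (2.71) and Zfp51 (2.72) at 3 months, and the sizes and order of these changes are uncertain. Nfe2l2, which encodes the antioxidant regulator NRF2, had the lowest adjusted p of all (1.39 ± 0.21, 0.00101) and was named after its value was seen. It was higher in 10 of 10 mice at 8 months than the mean at 3 months. Most genes called here show this, so it adds no support. The matrix genes Npnt (-0.90 ± 0.15) and Bgn (-1.10 ± 0.22) and the endothelial gene Vwf (-0.78 ± 0.17) fell. Lyz1 (0.76 ± 0.17), Lamp2 (0.87 ± 0.20), Xbp1 (0.64 ± 0.14), Id1 (1.11 ± 0.27) and Lyve1 (0.73 ± 0.17) rose.

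Type 2 pneumocyte genes had a median of 0.35 over time in control septa (adjusted camera p 0.0113), and 1 member passed over all genes and 5 adjusted over the list alone. Inflammatory genes had a median of 0.44 (adjusted p 0.00958), with 0 members over all genes and 4 adjusted over the list alone, namely Lcn2 (1.22), Cxcl2 (2.42), Il33 (1.04) and Ccl6 (0.66). Erythroid genes had a median of -1.59 (0 of 6 above 0, adjusted p 0.000118, 0 members over all genes and 5 adjusted over the list alone), and immediate early genes one of 0.39 (adjusted p 0.0223). With an estimated correlation the adjusted p was 0.565 for type 2, inflammatory and erythroid genes and 0.686 for immediate early genes. In the smoke-exposed mice, which are other animals, 96 of the 99 genes changed in the same direction between 3 and 8 months, with a median size of 0.66 against 1.15 log2 units in controls. Across the 10355 genes with the higher signal, the changes in both sets of mice correlated at 0.384. The smoke-exposed mice were taken at the same 2 times, so this agreement cannot tell age from other differences between those times. In these mice 144 genes passed, 20 of them shared with controls, among them Nfe2l2 (1.09 ± 0.20, adjusted p 0.00422), Npnt (-0.69 ± 0.15, adjusted p 0.0144), Prcd (1.99 ± 0.44, adjusted p 0.0157) and Lyve1 (0.67, adjusted p 0.0396). Cd14 changed by 0.28 ± 0.45 in the smoke-exposed mice (adjusted p 0.874). In control vessels Ly6a was the only gene called (1.79-fold, 0.84 ± 0.14, 10 against 8 mice, adjusted p 0.0241), with 1742 at an unadjusted p under 0.05. Of 100 splits 6, the real one included, called at least 1 gene, so chance cannot be excluded. Among other settings, the call for Ly6a ended with quantile normalization (adjusted p 0.0532), without mice 7 and 29 (0.158), with only the groups compared (0.135) and without any of 7 single arrays. In 1 fit over 76 arrays it held (adjusted p 0.00117), and 236 genes were called, 173 higher and 63 lower at 8 months. That fit shares 1 error per gene between tissues, adds a mouse block and keeps both mouse 25 arrays, and which of these moved the count was not tested. Antigen presentation genes had a median of 0.61 there (15 of 16 above 0, adjusted camera p 0.000352, 0.575 with an estimated correlation), and 5 of them, among them B2m (0.59) and H2-D1 (0.62), passed when adjusted over the list alone.

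**Figure D5:**
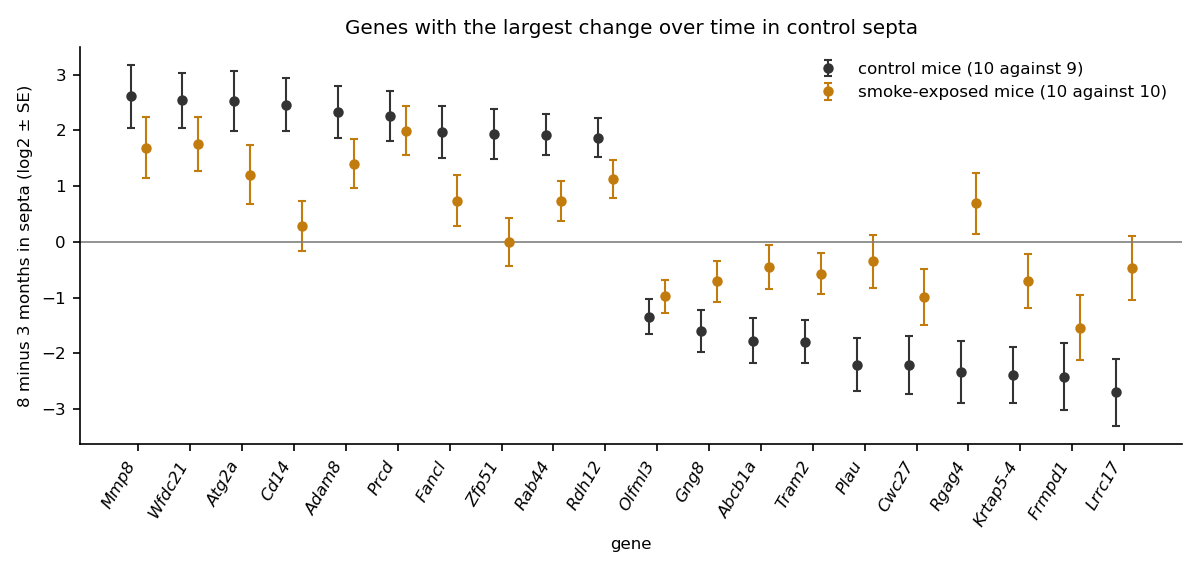
Change from 3 to 8 months in septa (log2 ± SE) of the 10 genes with the largest rise and the 10 with the largest fall in control mice, shown for control mice and for smoke-exposed mice. Mmp8 rose by 2.61 and Lrrc17 changed by -2.70 in control mice.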

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

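The comparisons and lists below were planned. Of the tests of explanations, those for time of day, unequal sexes and exchanged arrays were written down before they were run, and the others and the splits were chosen only after the result was seen.

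A sample far from the others was found in 3 of 32 tests, of Noxo1 and of array correlation in each of 16 groups, where chance gives about 1 in 20. Noxo1 in wild-type smoke-exposed septa at 8 months, replicate 1, was 5.57, against 2.49 to 3.27 in the others. The array correlation of knockout control vessels at 3 months, replicate 4, was 0.699, against 0.758 to 0.769. That of knockout control vessels at 8 months, replicate 3, was 0.779, against 0.75 to 0.757.

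A difference of smoke effects between tissues was tested and passed for LTO1 (-2.50) and Rnf130 (1.5), but both calls ended with mouse as a fixed factor (adjusted p 0.0892 and 0.113). Between genotypes, the interaction tests passed camera for 3 lists in septa at 3 months, 5 in septa at 8 months, 4 in vessels at 3 months and 6 in vessels at 8 months. Between times, 4 lists passed in septa and 4 in vessels, and between tissues 3 lists passed. None of these lists held with an estimated correlation. Among features without a gene name, which the comparisons do not use, 1 passed in the interaction in septa at 8 months and 31 with time in control septa.

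The clock gene Dbp ranged from 3.71 to 11.11 in septa and agreed between the tissues of a mouse (Pearson r 0.85, Spearman rho 0.79, n = 35, permutation p 1e-05, the smallest these can give, adjusted over 9 relations 2.2e-05, r 0.81 without the 2 farthest). With group means removed r was 0.80, which argues against amplification of single arrays. Of its variance 73.3% lay within groups in septa and 55.3% in vessels, so smoke, genotype and time do not set most of it in septa. In vessels they may set more of it. The share between groups was not tested, and means of small groups also differ by chance. Dbp correlated with the mean of Arntl and Npas2 at -0.61 in septa (rho -0.60, permutation p 6e-05, adjusted p 7.7e-05, -0.60 without the 2 farthest), which is consistent with a time of day that differed between mice. Times of collection were not analysed here, and a rhythm shifted in the mice themselves would give the same sign.

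Jchain in knockout vessels at 8 months (10.77 against 4.69, 9 against 9 mice, limma adjusted p 0.626, the lowest of that comparison, and exact p 0.0016, adjusted over 4 tests 0.00642) could stem from airway or lymphoid tissue dissected with the vessels, but with the airway and B cell list means as covariates the difference was 6.15 ± 1.31. With the sex-linked pattern as covariate it was 6.09 ± 1.31, so neither adjustment lowered it by much. The airway and B cell lists are not lists of plasma cell markers, so lymphoid tissue rich in plasma cells is not excluded. The Jchain means follow the labels and include the vessel arrays of mice 7 and 29, whose labels are in doubt. Without both mice the difference was 6.05 ± 1.30, and with the genotypes of these arrays exchanged 4.90 ± 1.41. The exact tests of Jchain were run because of its rank, which makes the exact p at 8 months too small. A genotype difference of vessels at both ages cannot be told apart from one limited to 8 months, since at 3 months the difference was 2.71 (exact p 0.0624, adjusted p 0.125).

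The sex-linked genes of mice 7 and 29 disagreed between tissues. Xist was 2.07 in septa and 12.92 in vessels of mouse 7, and 12.48 and 3.45 in mouse 29. Over 50 other genes the crossed pairing correlated at 0.536 and the labelled pairing at 0.298, a difference of 0.238, which is consistent with an exchange in 1 tissue. The same comparison paired 506 of 528 other pairs rightly (95.8%). Those pairs include mice of different exposures and times, and the genes were chosen with group means kept. This share may therefore be too high for mice 7 and 29, which are both controls at 8 months. Mixing of RNA would raise the lower sex marker, which reached only 3.45, against 6.19 in 72 other arrays. The 6.19 is an Eif2s3y signal of a female-pattern array, above the lowest male-pattern one (5.58), so this bound is lenient. The 3.45 is a Xist signal, which reached 4.95 in male-pattern arrays. The Noxo1 signal was 3.63 in septa and 7.03 in vessels of mouse 7, and 2.41 and 5.88 in mouse 29. Which tissue was exchanged is not settled, so the genotype of the arrays of both mice is uncertain.

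Splits redrew the labels 100 times, the real grouping counted among them. As many genes as observed were called in 1 split for tissue and 1 for time in control septa, in 3 for smoke between tissues, in 6 for time in control vessels and in 10 for smoke in wild-type septa at 3 months. In the 19 comparisons with 0 genes all 100 splits called as many, which a count of 0 makes certain. There the highest other split called 15 genes in wild-type vessels at 3 months and 17 for the smoke effect over time in septa, where 23 and 7 splits called any gene. Splits of this size may point to a structure of the samples, which was not tested. The genes at an unadjusted p under 0.05 with smoke in septa were matched by 2 splits.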

How the results depend on the processing

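The fits for the sex-linked pattern, for mice 7 and 29, for the 3 vessel arrays of low correlation and for Noxo1 without single arrays were tests chosen only after the data were seen.

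Of the counts 64 moved by over 1.5 times, and most of those that stayed were 0 in both fits, which says nothing of their stability. Of single genes 2396 kept their side of the threshold, 149 lost and 29 gained it. Of list results 115 held and 87 weakened. Most that held came from a second quantile normalization of values already normalized so, which could change them little. No result reversed. All 82 Noxo1 values kept their direction and, like the main fit, failed adjustment over all genes. Their leave-one-out differences were -1.44 to -1.18 in septa and -1.04 to -0.65 in vessels. With a correlation estimated per list the list calls outside tissue went from 77 to 1 and those of tissue from 23 to 13, because by construction it allows for genes of a list varying together. The tissue count ran from 5335 to 5994. Signals near background limit the calls for dim genes such as Noxo1. Where no cause is given, the cause was not tested.

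A single fit over 76 arrays shares 1 error per gene between tissues of unequal spread (0.738 in septa, 0.98 in vessels), adds a mouse block and keeps both mouse 25 arrays, and which of these moved the counts was not tested. It called 0 genes for smoke in wild-type septa at 3 months, 5 for time in control septa, 236 for time in control vessels, 34 for smoke in wild-type and 23 in knockout vessels at 3 months, 2 in knockout vessels at 8 months, 5 for mean smoke in vessels, 27 and 1 for genotype in vessels at 3 and 8 months, 13 for the interaction in vessels at 3 months, and 1 for smoke over time in vessels. With only the groups compared, smoke in wild-type septa at 3 months gave 0 and time in vessels 0. Time in control vessels (1 gene) gave 0 with quantile normalization, 5 without genes under the 25th percentile of signal, 3 with the mean of probes, 4 with array weights, 2 with the sex-linked covariate, 0 without mice 7 and 29, and 2 with both mouse 25 arrays. Mean smoke in vessels gave 1 with the mean of probes and 1 with both mouse 25 arrays (Tmem203). Smoke between tissues (2 genes) gave 1 without mice 7 and 29, 1 without the 3 low arrays, 0 with mouse as a fixed factor, 0 without the knockout and 0 without the wild-type 3-month pairs, and 1 and 1 without those at 8 months. A replicate block gave 1 for smoke in knockout vessels at 8 months and 0 for time in vessels, and changed no other count by over 1.5 times. Arrays sharing a replicate number correlated at 0.022 (36 pairs, 6 over 0.1), others at -0.005. Septa and vessels of a mouse reached only 0.04 by the same measure, so it cannot decide whether the number pairs arrays.

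Leaving out single arrays gave 0 to 1 gene for smoke in wild-type septa at 3 months (0 without control replicate 3 or 4), 0 to 3 in knockout septa at 8 months (3 without control replicate 1), 0 to 1 in knockout vessels at 3 months (1 without control replicate 2 or 3), 0 to 1 for mean smoke in vessels (LTO1 without knockout control 3-month replicate 1, Tmem203 without knockout control 3-month replicate 2, wild-type control 3-month replicate 3, wild-type control 8-month replicate 4, wild-type smoke 3-month replicate 3 or wild-type smoke 8-month replicate 2), and 0 to 1 for genotype in septa at 3 months (Npr3, without wild-type smoke replicate 5). It gave 0 to 2 for the interaction in vessels at 3 months (2 without knockout smoke replicate 3, 1 without replicate 5), 0 to 1 for smoke over time in vessels (1 without wild-type smoke 3-month replicate 2), and 0 to 6 for time in vessels (6 without knockout control 8-month replicate 1). For time in vessels 13 of the 18 arrays moved the count, and Ly6a was lost without knockout control 3-month replicate 3, knockout control 8-month replicate 4 or 5, wild-type control 3-month replicate 4, or wild-type control 8-month replicate 2, 3 or 4. Time in control septa ranged from 29 (without knockout control 3-month replicate 3) to 108, with 38 and 59 without wild-type control 3-month replicates 4 and 1.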

Other observations

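All tests in this part were chosen only after the results were seen.

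Immediate early genes varied between mice as the clock genes did, and alike in both tissues. Egr1 ranged from 9.14 to 14.31 in septa and correlated between septa and vessels of a mouse at 0.85 (Spearman rho 0.79, n = 35, permutation p 1e-05, the smallest these can give, adjusted over 9 relations 2.2e-05, 0.83 without the 2 farthest). Egr1 and Dbp did not track each other in septa (Pearson r -0.02, rho 0.01, permutation p 0.88). Of the variance of Egr1, 65.2% in septa and 72.6% in vessels lay within groups. Over 33 mice and 20710 genes the median correlation between tissues was 0.042, and 10 genes exceeded 0.74, the 95th percentile of the highest value in 100 permutations. These were Xist (0.95), Eif2s3y (0.9), Dbp (0.88), Egr1 (0.85), Erdr1 (0.8), Nr4a1 (0.78), Nr1d2 (0.76), Fos (0.76), Pfkfb3 (0.75) and Btg2 (0.75). List medians were highest, after the sex-linked genes, for erythroid (0.5), immediate early (0.49), neutrophil (0.34) and clock genes (0.31).

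In knockout septa at 3 months Fkbp5 (1.33 ± 0.32), Klf15 (1.01), Tsc22d3 (0.51) and Angptl4 (1.16), all induced by glucocorticoids, had differences from wild-type with an adjusted p of 0.46. A hypothesis of a differing glucocorticoid response was tested with 12 other such genes in vessels at 3 months, where the difference of 0.21 had an exact p of 0.299 (adjusted over 4 tests 0.55). These vessels came largely from the same mice as the septa, so the test is not independent. In them Tsc22d3 differed by 0.61 ± 0.15, Klf15 by 0.83 ± 0.28, Angptl4 by 0.53 ± 0.41 and Fkbp5 by 0.08 ± 0.34. None of these passed adjustment over all genes. The same 12 genes differed by 0.27 in septa at 3 months (8 of 12 higher, exact p 0.228), and by -0.09 in septa and -0.12 in vessels at 8 months, so the hypothesis stays open.

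By sex-linked genes 26 arrays had a female and 50 a male pattern, and 33 of 35 mice with both tissues had the same pattern in both. Xist separated the patterns, at 10.8 or more against 4.95 or less. Eif2s3y overlapped, with up to 6.19 in the female and 5.58 or more in the male pattern.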
